A study of Solanum lycopersicum with 8 samples.

How the data were processed

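Messenger RNA was sequenced from tomato (Solanum lycopersicum, cultivar M82), in isolated gland cells of type VI trichomes and in leaves from which the trichomes had been scraped. Type VI trichomes are leaf hairs that carry a head of secretory gland cells on a short stalk. Each tissue has 4 libraries from 4 separate collections. Plants were 5 weeks old and were grown at 28 °C and 250 µE of light, per the labels' protocols, which also say that the shaved leaves came from the plants used for the trichome preparation. RNA was isolated with an RNeasy kit and libraries were made with a TruSeq RNA kit, per the labels' protocols. The labels give a different genotype for each tissue: the leaf libraries are labelled as the anthocyanin free (af) mutant and the trichome libraries as a complemented line. If those labels hold, genotype and tissue cannot be separated in any comparison made here. The genotype labels conflict with the protocols' statement that both tissues came from the same plants, and which of them is right is not settled.

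The deposited files hold raw HTSeq counts of reads per gene, one file per library, with no normalization. Trimmomatic, TopHat2, SAMtools and HTSeq are named in the submitters' processing notes, without versions. The genome build, the annotation, the aligner settings and whether counting used strand are not given in the sources used here. Reads from overlapping or antisense genes can therefore not be told apart, and near-identical gene copies are uncertain. HTSeq's 5 summary lines were left out of library sizes and tests. They took 13.3% ± 0.829 of all counted lines in leaf and 21.1% ± 2.61 in trichome libraries (mean ± SD, n = 4 each). Gene totals ran from 19209754 to 34941715 counts per leaf library and from 24596280 to 26514416 per trichome library. A count of 3, the limit that a count of 0 allows, stood for 0.0859 to 0.156 CPM in leaf and 0.113 to 0.122 CPM in trichome libraries, scaled to gene totals alone, without the TMM factors used for levels below. Such limits and intervals cover counting error only, since reads without molecular identifiers are not independent molecules.

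The files pair no gene ID with a name. The reference table given for this work (RefSeq assembly SLM_r2.1) holds symbols but none of the IDs in the files: 0 of 34725 IDs matched directly. Names come from a list of 161 published ID assignments fixed before the data were examined, of which 160 IDs are in the files. For 103 of them the table holds a symbol for the gene, and the chromosome and relative position along it were compared, with a difference of up to 5 percentage points allowed: 102 passed and 1 failed, and the failing name is not used. Of the 102, 81 are printed under the table's symbol, 17 under a synonym it gives and 4 under a name it does not hold. These 4 and the other names rest on the published list alone, and such genes are introduced as "listed as". The neighbouring models PHS1 and NDPS1 overlap in the reference, and which ID belongs to which name is not settled. A further 36 lists defined by keywords in product descriptions were void, because no product descriptions were given.

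Counts were tested with edgeR 4.0.16 in R 4.3.3 (quasi-likelihood fit and test, TMM factors, filterByExpr, no block), and a gene was called at a Benjamini-Hochberg adjusted p under 0.05 over all tested genes. Levels are TMM-normalized read counts scaled to library size (CPM) over all genes, computed from the deposited counts, given as mean ± SD with n = 4. Standard errors of log2 fold changes were computed as the fold change over the square root of the F statistic and are approximate. Gene lists with at least 3 tested members were tested with camera (limma 3.58.1) at a preset correlation of 0.01, with Benjamini-Hochberg adjustment over 20 lists; camera with an estimated correlation and fry were run beside it. Shares of counts were compared with exact two-sided permutation tests over 70 splits, where the smallest p is 0.0286; these splits ignore the pairing of the libraries, and labels exchanged within the 4 collections, an alternative chosen after seeing the data, give 16 arrangements and a smallest p of 0.125. The tests' p-values treat the 4 collections as independent samples, per the labels.

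The collection numbers were taken to pair the libraries, because the labels' protocols take both tissues from the same plants. The genotype labels conflict with that statement. The deviations of same-numbered libraries from their group means correlated at 0.0990, 0.136, 0.188 and 0.166. Between leaf and trichome libraries of different numbers they ran from -0.197 (leaf 1 with trichome 3) to 0.135 (leaf 2 with trichome 1), so the ranges overlap. A fit with the collection as a block was run as an alternative. The other alternatives were RLE and upper-quartile factors, library size alone, no filter, a filter of at least 5 CPM in 4 libraries, DESeq2 1.42.0, limma-voom, leaving out each library or collection, and leaving out the 100 most abundant genes.

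Named genes follow a rule set before the data were examined: the 10 highest and 10 lowest fold changes among called genes with a mean of at least 30 CPM and the same sign in all 4 collections (of those without a name, at most 2 per direction are printed), the 4 most abundant tested members of each list described, and any member of the terpene synthase, MEP, acylsugar, flavonoid and trichome regulator lists. The tests were checked on counts simulated from the means, dispersions and library sizes of these 20409 tested genes. Of 100 genes changed 2-fold 18.0% were called, and of 100 changed 4-fold 81.0%, with 8 false calls among 20209 unchanged genes. So few changed genes make the adjusted threshold stricter than in the data, where 72.4% of tested genes were called. The shares therefore do not measure power in this comparison, and what absence of a call says about 2-fold changes was not measured.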

Results

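RNA from gland cells of type VI trichomes was compared with RNA from trichome-shaved leaf in 4 collections, with 4 libraries per tissue. The deposited raw counts came to between 19209754 and 34941715 per leaf library and between 24596280 and 26514416 per trichome library. Of 34725 genes in the files, 20409 had enough counts to be tested. Correlations of log CPM ran from 0.923 to 0.971 between leaf libraries, from 0.960 to 0.981 between trichome libraries and from 0.515 to 0.591 between tissues. No pair of libraries agreed within sampling noise, and each counts as 1 sample.

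The comparison asks which transcripts set the gland cells apart from the leaf below them. By camera at a preset correlation, 5 of 20 gene lists lay towards the glands: terpene synthases (4 of 4 tested genes rose), the terpene cluster on chromosome 8 (7 of 8, 1 fell), the plastid isoprenoid (MEP) pathway (7 of 8, 1 fell), acylsugar synthesis (7 of 7) and flavonoid synthesis (7 of 10, 2 fell). The terpene synthase list and the cluster share PHS1 and NDPS1, so they are not separate results, and NDPS1 makes a precursor rather than a terpene. Another 4 lists lay towards the leaf: photosystems, Calvin cycle, photorespiration and glycoalkaloid synthesis. With an estimated correlation 0 lists passed. In all, 14780 genes (72.4% of those tested) differed at an adjusted p under 0.05 in edgeR's quasi-likelihood test, 6925 of them higher and 7855 lower in trichome. Of these, 14523 had the same sign in all 4 collections. By at least 2-fold, 4563 genes were higher and 6451 lower. At a log2 fold change of 5 or more there were 591 genes on the trichome side and 1932 on the leaf side. The leaf libraries are labelled as the af mutant and the trichome libraries as a complemented line, so a difference between tissues is also one between genotypes if these genotype labels hold. The labels' protocols, which take both tissues from the same plants, conflict with them.

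PHS1 (Solyc08g005670), which makes monoterpenes such as beta-phellandrene, had 3.55 ± 1.89 CPM in leaf and 1931 ± 495 in trichome (SD, n = 4), a log2 fold change of 9.09 (SE 0.56, edgeR adjusted p = 1.33e-06). The neighbouring gene NDPS1 (Solyc08g005680), which makes the precursor neryl diphosphate, had 11.2 ± 6.11 and 3588 ± 963 CPM (log2 8.33). TPS12 (Solyc06g059930), a sesquiterpene synthase, reached 6670 ± 1606 CPM in trichome against 35.2 ± 26.4 in leaf, and MTS1 (Solyc01g105890), a linalool synthase, rose by 3.55 on the log2 scale, or by 4.42 without leaf replicate 4. Which of these neighbouring IDs carries which name is not settled for PHS1 and NDPS1. All 4 tested members of the list rose, as they did adjusted over the list alone (4 of 4; camera adjusted p = 0.0080; adjusted p = 0.345 with an estimated correlation). The low leaf levels of trichome genes shared an order: among 70 genes at 300 CPM or more in trichome and a log2 fold change of 7 or more, 39 were highest in leaf replicate 2, then 1, 3 and 4. The cluster of terpene genes on chromosome 8 also holds PHS1 and NDPS1. Of its 8 tested members 7 rose and 1 fell (7 and 1 adjusted over the list alone, camera adjusted p = 0.0039, adjusted p = 0.345 with an estimated correlation).

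Of the MEP pathway, which makes the plastid precursors of monoterpenes, 7 of 8 genes rose and 1 fell (7 and 1 adjusted over the list alone; camera adjusted p = 0.0125; adjusted p = 0.393 with an estimated correlation). The 2 copies of the first enzyme went opposite ways: DXS2 (Solyc11g010850) rose from 190.5 ± 50.5 to 1740 ± 663 CPM, whereas a gene listed as DXS1 (Solyc01g067890) fell from 486.8 ± 139 to 122.2 ± 9.32 CPM. HDS (Solyc11g069380) reached 4200 ± 1870 CPM in trichome, a log2 fold change of 3.05. Of the mevalonate list, all of whose 4 members encode HMG-CoA reductase, the enzyme that commits carbon to the cytosolic pathway, 2 rose and 2 fell (2 and 2 adjusted over the list alone; camera adjusted p = 0.530). HMGR4 (Solyc03g032020) rose from 9.98 ± 1.81 to 240.8 ± 44.8 CPM and HMG2 (Solyc02g038740) by 5.09 on the log2 scale, while HMGR (Solyc02g082260) fell by 0.82.

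**Figure D1:**
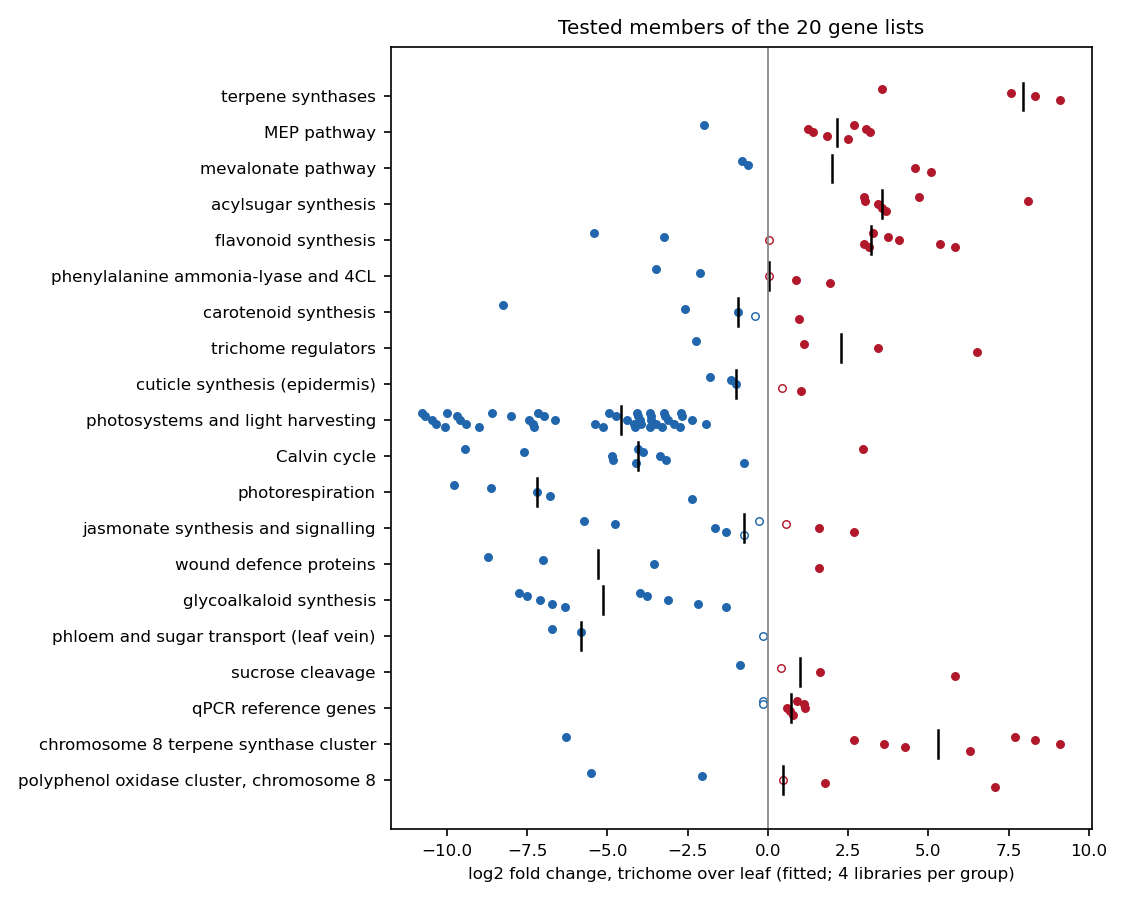
Log2 fold change of every tested member of the 20 gene lists, trichome over leaf, with 4 libraries per group. Filled points passed the adjusted p of 0.05, open points did not, and black bars mark list medians; all 44 photosystem members lie to the left of 0 and all 7 acylsugar members to the right.

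All 7 genes of acylsugar synthesis, which builds the sticky sugar esters of glandular hairs, rose (7 adjusted over the list alone; camera adjusted p = 0.0125; adjusted p = 0.457 with an estimated correlation). Before the data were examined, this list was fixed as a marker of tip cells of other glandular hairs, types I and IV. Whether such cells came along in the type VI preparation was not tested. These values therefore cannot assign the transcripts to type VI glands. Most of the 7 genes were low in CPM. IPMS3 (Solyc08g014230) rose from 0.114 ± 0.104 to 30.5 ± 13.1 CPM and ASAT3 (Solyc11g067270) from 3.05 ± 3.28 to 79.1 ± 23.4. In trichome, a gene listed as ASAT4 (Solyc01g105580) had 2.23 ± 1.62 CPM, and its call was lost without leaf replicate 1 (adjusted p = 0.0605), leaf replicate 3 (0.0534), trichome replicate 2 (0.0588), collection 1 (0.0941) or collection 3 (0.0807). Without collection 1 (0.0755) or 3 (0.0745), a gene listed as ASAT2 (Solyc04g012020) lost its call, so that 5 of 7 were then called. Without leaf replicate 2 the log2 fold change was 6.25 in place of 3.67 for ASAT4, 4.66 in place of 3.01 for ASAT2, 5.77 in place of 4.69 for ASAT3 and 8.88 in place of 8.09 for IPMS3 (7.40 without collection 4). In trichome replicate 4, ASAT2 had 1.53 CPM (9.02 to 12.5 in the other trichome libraries) and ASAT4 0.0986 (2.29 to 4.03). ASAT1 (Solyc12g006330), ASAT3 and genes listed as AACS1 (Solyc07g043630) and AECH1 (Solyc07g043680) were also lowest there among trichome libraries. IPMS3 was highest there (49.7 CPM). The cause was not tested.

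CHS1 (Solyc09g091510), a chalcone synthase of the flavonoid list, had 7500 ± 3143 CPM against 182.4 ± 152 in leaf, a log2 fold change of 5.36, or 6.01 without leaf replicate 2. F3'H (Solyc03g115220) rose by 5.83 and a gene listed as FLS (Solyc11g013110), flavonol synthase, by 3.73 on the log2 scale. MYB12 (Solyc01g079620), a regulator of flavonol genes, rose by 3.14. Of the 10 genes of the list, 7 rose and 2 fell (7 and 2 adjusted over the list alone; camera adjusted p = 0.0125; adjusted p = 0.544 with an estimated correlation). The list's call was also lost without the 100 most abundant genes of these libraries (adjusted p = 0.514), an alternative chosen after seeing the data. The 2 that fell, DFR (Solyc02g085020) and ANS (Solyc08g080040), act in the anthocyanin branch; in collection 4 both were higher in trichome (1.38 against 0.245 CPM for DFR and 2.91 against 1.44 for ANS). Leaf replicate 2 held 95.8 CPM of DFR and 100.4 of ANS, against at most 14.6 and 6.03 in the other leaf libraries. Without leaf replicate 2 DFR had a log2 fold change of -3.55 in place of -5.41. The call of DFR was lost with limma-voom (adjusted p = 0.252). The call of ANS was lost without leaf replicate 2 (log2 -0.41, adjusted p = 0.431), without any single trichome library (adjusted p 0.0706 to 0.0769), without collection 1 (adjusted p = 0.0608), 2 (0.395) or 3 (0.0647), with limma-voom (log2 -1.39, adjusted p = 0.391) and with the replicate block (log2 -1.35, adjusted p = 0.223).

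CHI1 (Solyc05g010320), chalcone isomerase, is the gene mutated in af. It had 283.7, 271.8, 120.4 and 99.2 CPM in the 4 leaf libraries and 1421, 1687, 1499 and 1531 CPM in the trichome libraries, a log2 fold change of 2.99 (SE 0.38, edgeR adjusted p = 9.59e-05). The libraries labelled af were lower in all 4 collections, as they were for CHS1, F3H and F3'H, so this level does not separate the tissue from the labelled genotype.

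Of the regulators of trichome development and terpene genes, 3 of 4 tested genes rose and 1 fell (3 and 1 adjusted over the list alone; camera adjusted p = 0.215). EOT1 (Solyc02g062400) rose by 6.52 and MYC1 (Solyc08g005050) by 3.43 on the log2 scale. The third riser, a gene listed as MX1 (Solyc02g088190), up by 1.13 and higher in 3 of 4 collections, lost its call in 11 of 21 alternatives, such as upper-quartile factors (adjusted p = 0.0519), which leaves 2 of 4. A gene listed as Woolly (Solyc02g080260), which acts in the initiation of hairs, fell by 2.25.

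**Figure D2:**
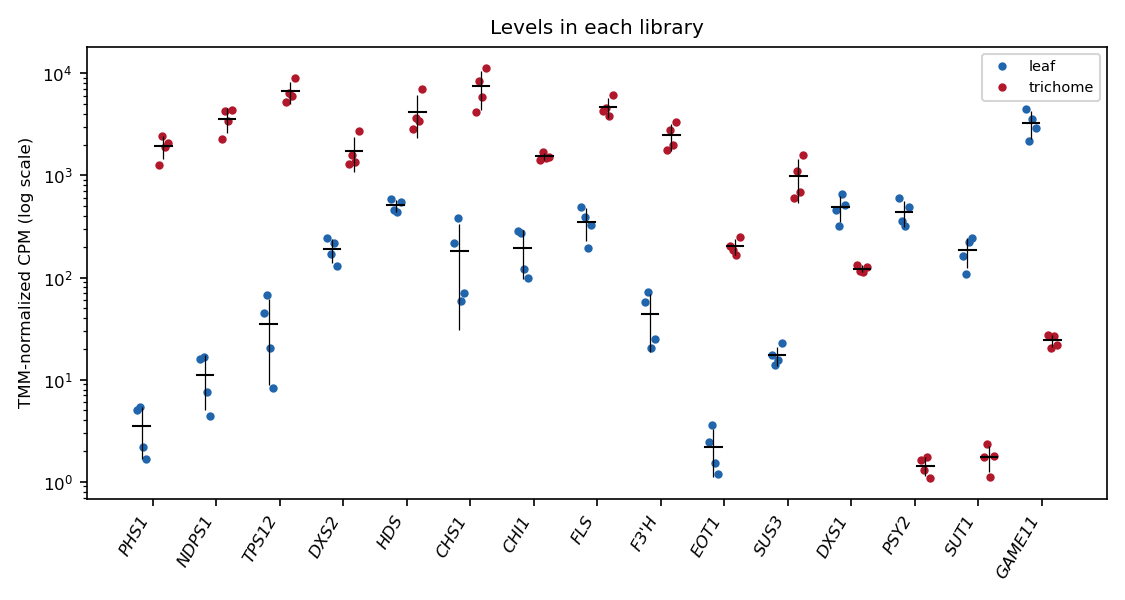
TMM-normalized CPM in each of the 8 libraries for 15 genes, on a log axis, with leaf in blue and trichome in red, means as black bars and 1 SD as lines. PHS1 lies at 1.68 to 5.36 CPM in leaf and at 1267 to 2451 in trichome.

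All 44 tested genes of the photosystem and light-harvesting list fell (44 adjusted over the list alone; camera adjusted p = 6.14e-16; adjusted p = 0.345 with an estimated correlation). Trichome libraries kept 0.0577% to 26.4% of the leaf level. The list also holds electron carriers, genes listed as plastocyanin (Solyc04g082010, 4.76% of leaf) and FNR (Solyc02g083810, 19.5%). Of the 29 chlorophyll a/b-binding genes, 17 kept under 1% and 11 kept at least 4%. CAB4 (Solyc07g047850), for example, had 5889 ± 910 CPM in leaf and 677.0 ± 177 in trichome (11.5%). These genes include near-identical copies, so the split of reads between them is uncertain. In the Calvin cycle list, 10 of 11 genes fell and 1 rose (10 and 1 adjusted over the list alone; camera adjusted p = 0.0010; adjusted p = 0.358 with an estimated correlation; adjusted p = 0.0627 without the 100 most abundant genes, an alternative chosen after seeing the data). RBCS-2A (Solyc03g034220), a small subunit of Rubisco, fell from 10916 ± 2115 to 733.3 ± 84.5 CPM. All 5 genes of photorespiration fell (5 adjusted over the list alone; camera adjusted p = 0.0035; adjusted p = 0.345 with an estimated correlation). A gene listed as glycolate oxidase (Solyc07g056540) fell from 3472 ± 937 to 3.94 ± 0.411 CPM.

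**Figure D3:**
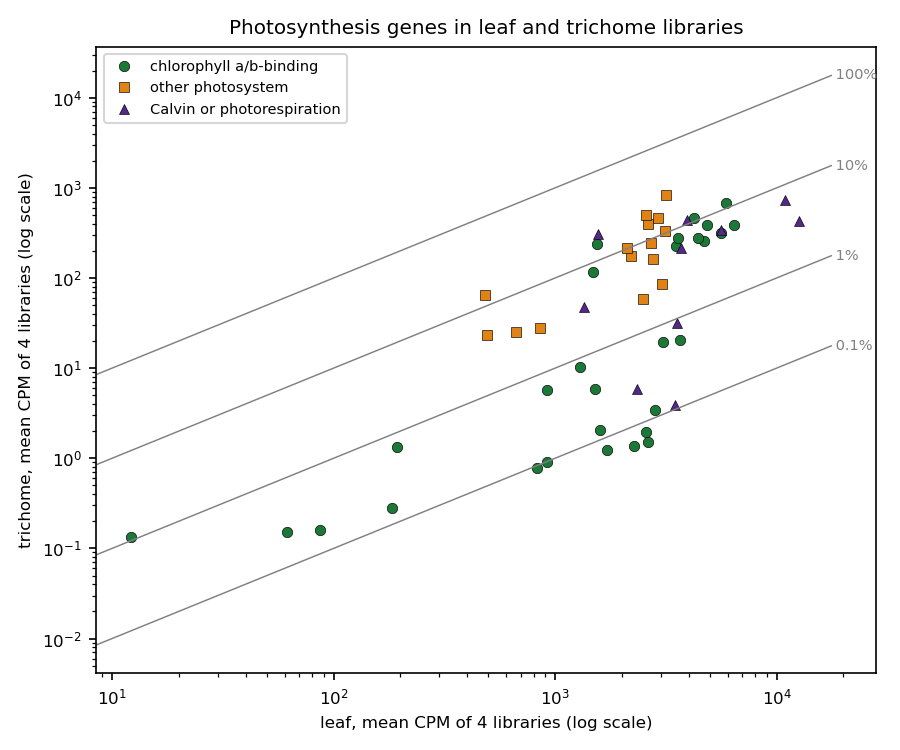
Mean CPM of 44 genes of the photosystem and light-harvesting list and 10 Calvin cycle and photorespiration genes, leaf against trichome, 4 libraries each, on log axes. Calvin cycle and photorespiration genes are drawn only from 1000 CPM in leaf upwards, which leaves out the 1 riser of the Calvin cycle list. Grey lines mark trichome levels of 100%, 10%, 1% and 0.1% of leaf. The chlorophyll a/b-binding genes spread from 0.0577% to 15.5% of the leaf level.

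All 10 genes listed for glycoalkaloid synthesis, the pathway to bitter steroidal alkaloids, fell, 1 of them under a listed name that the reference table contradicts (10 adjusted over the list alone; camera adjusted p = 5.08e-04; adjusted p = 0.358 with an estimated correlation). GAME11 (Solyc07g043420) went from 3290 ± 995 to 24.2 ± 3.43 CPM. Of the sucrose transporters, 2 of 3 fell and 1 was not called (2 adjusted over the list alone; camera adjusted p = 0.167). SUT1 (Solyc11g017010), the phloem loader, fell by 6.73 on the log2 scale. In the carotenoid list 1 of 5 genes rose and 3 fell (1 and 3 adjusted over the list alone; camera adjusted p = 0.293), and PSY2 (Solyc02g081330), a phytoene synthase, fell from 438.8 ± 127 to 1.44 ± 0.295 CPM. In the cuticle list, a marker of the other epidermal cells, 1 of 5 genes rose and 3 fell (1 and 3 adjusted over the list alone; camera adjusted p = 0.736): CER6 (Solyc02g085870) rose by 1.03 and CD2 (Solyc01g091630) fell by 1.00 on the log2 scale. CD1 (Solyc11g006250), which fell by 1.15, lost its call in 8 of 21 alternatives, such as without leaf replicate 1 (adjusted p = 0.0866), which leaves 2 fallen.

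Among the genes without a name, Solyc07g008210 had 81.4 ± 61.2 CPM in leaf and no count in any trichome library, at least 1681-fold lower against a floor of 3 counts over the group when leaf replicate 2, the highest at 169.1 CPM, is left out of the leaf mean. Solyc04g054730 had a log2 fold change of -12.01, or -7.39 without leaf replicate 4, which held 740.8 CPM against at most 16.0 in the other leaf libraries, and -13.42 without trichome replicate 4; its call was lost with limma-voom (log2 -8.85, adjusted p = 0.0769). Solyc01g006440 rose from 0.197 ± 0.0797 to 74.8 ± 33.3 CPM and Solyc09g092620 from 1.27 ± 0.786 to 477.8 ± 136 CPM.

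Libraries also differed in composition. The 10 most abundant genes took 7.60% ± 0.585 of counts in leaf and 13.4% ± 2.68 in trichome (exact two-sided permutation p = 0.0286, adjusted p = 0.0381 over 8 measures, n = 4 each; that test ignores the pairing, and with labels exchanged within collections p was 0.125, the smallest that 16 arrangements give), and the 100 most abundant 28.7% ± 2.62 and 33.2% ± 3.98 (exact permutation p = 0.171, adjusted p = 0.196). With library size alone in place of TMM factors, the median of all genes moved by -0.215 on the log2 scale and 38.6% of called genes were higher in trichome, against 46.9%. In all, 9 of 20 lists passed camera's test, and 0 passed with an estimated correlation.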

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

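The tests of trichome material in leaf, of leaf cells and gene copies in the trichome libraries and of reads outside genes were chosen after the results were seen; the counts over other splits were planned.

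Other groupings of the 8 libraries were fitted in the same way over all 35 splits into 4 and 4. For the number of genes called, 1 split, the real one, reached 14780, and the highest other split gave 0 calls in edgeR's test (up to 1789 genes at an unadjusted p under 0.05; no other tool was run on the splits). For genes called by at least 2-fold, 1 split reached the real 11014 and the highest other gave 0. The other splits mix the tissues in each group, which widens the spread within groups and leaves few calls to expect, so these 2 counts say little about chance. Among the 8 splits that part all 4 pairs, the real one gave 14780 genes and 9 lists and the highest other 0 genes and 9 lists; 8 splits are too few for a share under 0.05. For the gene lists, 5 of the 35 splits reached the real number of 9 and the highest other also gave 9, so chance cannot be excluded for the number of lists by this count. The 4 other splits with 9 lists set 3 libraries of each tissue against 1 and so keep part of the tissue difference; the 18 splits with 2 libraries of each tissue per group gave at most 5 lists.

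Trichome genes were measurable in the shaved leaf in a shared order. Of 70 genes with at least 300 CPM in trichome and a log2 fold change of 7 or more, 39 (55.7%) followed the order leaf 2, leaf 1, leaf 3, leaf 4, the most frequent one and so picked from the data, and 18 the next most frequent. Of 16998 other tested genes in the same range of leaf CPM, 5.95% followed that order, and no order took over 7.48%. The median log2 ratio of leaf 2 over leaf 4 was 0.0171 over all tested genes, a value that TMM normalization holds near 0. For these genes it was 1.73 (SD 0.948). A single factor per library moves all genes alike and cannot give this gap, which argues against scaling of the leaf libraries as its source. Gene totals rose from 19209754 in leaf 1 through 23065238 and 29377778 to 34941715 in leaf 4. The 18 genes of the next most frequent order fell from leaf 1 to leaf 4. Sources that weigh more in libraries with fewer counts were not tested, so depth stays open. Trichome material left on the leaves may account for the shared order; its amount was not estimated, because these genes were chosen by their fold change. Expression in the leaf itself that differs between collections stays open and was not tested.

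Genes of the photosystem and light-harvesting list kept unequal shares of their leaf level in the trichome libraries, with a median of 4.26%. Leaf cells carried into the preparation are argued against as the whole cause: 8 of 73 other genes with at least 1000 CPM in leaf lay under 10% of the photosystem median in all 4 trichome libraries. Reads shared between near-identical copies cannot be told apart from expression, neither in the chlorophyll a/b-binding family, where 17 of 29 members kept under 1%, nor in the 15 members outside it, since nothing in the tables separates the copies. All 15 kept over 10 times the lowest share (0.113%) of the Calvin cycle and photorespiration lists, but that test was set aside, because this share measures no sharing of reads. Stalk or epidermal cells cannot be told apart from gland expression either, because the cuticle list, whose median fell by 1.00 on the log2 scale over members that went both ways, has no pure gland sample beside it. Transcription in the gland cells, a difference of tissue, remains an open hypothesis.

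Reads outside annotated genes took 11.1% of lines in trichome libraries, against 3.81% to 4.21% in leaf libraries, a signal in data that the comparisons do not use. Genomic DNA would put counts on silent genes, and the trichome libraries had on average 2070.5 more genes at 0 than the leaf libraries. That number also depends on how many genes each tissue expresses, so it cannot decide whether genomic DNA took part. Transcripts or introns outside the annotation could give the difference of 7.11 percentage points, which cannot be told apart from other sources without the reads. Reads that mapped to more than 1 place were also above leaf, at 5.31% against 2.87% to 4.44%.

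Single libraries stood apart from the other 3 of their group in 19 of 202 groups tested, where chance sets apart about 1 in 20 if values are normal. Untransformed CPM need not be normal and the groups share libraries, so no excess over chance was measured. Trichome replicate 4 was highest for MTS1 (459.9 CPM), HDR (2651 CPM), a gene listed as PAL (Solyc09g007900, 193.0 CPM), Cab-1A (622.4 CPM), a gene listed as Rubisco activase (Solyc10g086580, 542.8 CPM) and COI1 (333.1 CPM), and had 14325 genes at 0. Leaf replicate 2 was highest for a gene listed as ASAT4 (0.595 CPM), F3'5'H (40.9 CPM), DFR (95.8 CPM), ANS (100.4 CPM) and a gene listed as ASAT2 (3.01 CPM). Leaf replicate 4 was highest for Solyc04g054730 (740.8 CPM), a gene listed as PI-I (5777 CPM), Solyc08g074630 of the polyphenol oxidase cluster (485.7 CPM) and reads mapping to several places (4.44%). Leaf replicate 3 was lowest for PAL3 (165.3 CPM), leaf replicate 1 highest for GPAT6 (135.2 CPM), and trichome replicate 2 had the smallest trichome total (24596280 counts).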

How the results depend on the processing

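The fits without a whole collection for named genes, the runs of lists and named genes without the 100 most abundant genes, the exchange of labels within collections and the glycoalkaloid list without the member whose name the reference contradicts were chosen after seeing the data; the other alternatives were planned. The alternative without organelle-encoded genes was not run, since no ID shows such a gene. Called genes numbered from 10944 (stricter filter, 14722 genes tested) to 16208 (no filter), against 14780, with 0 shared calls of opposite sign under any alternative. The replicate block gave 14522 calls, kept 14200 of the 14780 and left the number of lists at 9; among named genes it ended the calls of ANS, PI-I, Lin6, Solyc08g074630 and Solyc08g074680 and changed no other call.

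The list results depend on the test. With an estimated correlation 0 lists passed, at adjusted p of 0.345 for terpene synthases, photosystems, photorespiration and the chromosome 8 cluster, 0.393 for MEP, 0.457 for acylsugars, 0.544 for flavonoids and 0.358 for Calvin cycle and glycoalkaloids. With fry, which compares a list with no other genes, 16 lists passed, and mevalonate (6.96e-05), carotenoids (6.96e-05), trichome regulators (2.99e-05), phloem (4.35e-06), sucrose cleavage (6.79e-05), qPCR reference genes (1.32e-04) and the polyphenol oxidase cluster (0.00136) were added. Without the 100 most abundant genes 5 lists passed: flavonoids (0.514) and Calvin cycle (0.0627) lost the call. Terpene synthases and photorespiration then had 2 tested members each, too few to test. That alternative removes abundant list members by construction. The share of counts in the 10 most abundant genes differed by 4.60 to 6.69 percentage points when single libraries were left out, and without any leaf replicate the exact permutation p was 0.0571, with fewer samples. With labels exchanged within collections, which keeps the pairing (replicate block), the difference of 5.79 had an exact permutation p of 0.125, the smallest that 16 arrangements give.

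A gene listed as PAL (Solyc09g007900), not called with all libraries, fell without replicate 4 (log2 -0.93) and ranged up to 0.60 without replicate 3; the cause was not tested. Of the 109 genes under the naming rule, 102 were called: 87 kept the call under every alternative that gave a value and 15 lost it under at least 1. Of the 7 not called, 5 stayed so and 2 changed. The acylsugar genes lie at 0.114 to 3.05 CPM in leaf.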

Other observations

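The shuffles of neighbouring genes were planned before their result was seen, and their threshold of 5 on the log2 scale was set after the counts at that size were known.

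Polyphenol oxidase genes lie in a cluster on chromosome 8, where 2 of 5 tested members rose and 2 fell (2 and 2 adjusted over the list alone; camera adjusted p = 0.477). The fallen count was 0 without leaf replicate 4, without collection 4 and with the replicate block: Solyc08g074630 had 485.7 CPM in leaf replicate 4 and, without it, a log2 fold change of -1.02 (adjusted p = 0.0916), and Solyc08g074680 lost its call in 9 of 21 alternatives. Solyc08g074620 had 11006 ± 1880 CPM in trichome and 82.3 ± 84.8 in leaf (SD, n = 4), a log2 fold change of 7.06, or 8.05 without collection 2, whose leaf library held 201.2 CPM. In the sucrose cleavage list, SUS3 (Solyc07g042550), a sucrose synthase, rose from 17.4 ± 3.75 to 992.4 ± 455 CPM, while the vacuolar invertase TIV1 (Solyc03g083910) fell by 0.86 on the log2 scale, and 2 of 4 genes rose and 1 fell (2 and 1 adjusted over the list alone; camera adjusted p = 0.477). The other riser, Lin6 (Solyc10g083290), lost its call in 15 of 21 alternatives, such as RLE factors (adjusted p = 0.0504), which leaves 1 of 4. Of the jasmonate list 2 of 9 genes rose and 4 fell (2 and 4 adjusted over the list alone; camera adjusted p = 0.735): AOS2 (Solyc11g069800) rose by 2.68 and LoxD (Solyc03g122340) fell by 4.77 on the log2 scale (log2 -4.13 without collection 4). Of 4 wound defence genes 1 rose and 3 fell (1 and 3 adjusted over the list alone; camera adjusted p = 0.823): LAPA1 (Solyc12g010040) rose by 1.59 and TD2 (Solyc09g008670), a threonine deaminase, fell by 8.72. The third that fell, a gene listed as PI-I (Solyc09g084470), with 5777 CPM in leaf replicate 4 (log2 -7.00, or -2.76 without that library) and lower in trichome in 3 of 4 collections, lost its call with the replicate block (log2 -3.09, adjusted p = 0.226), with limma-voom (adjusted p = 0.289) and without collection 4 (adjusted p = 0.0870), which leaves 2 fallen. Among leaf libraries, TD2 (1257 CPM) and LoxD (293.7 CPM) were also highest in leaf replicate 4, whereas LAPA1 was not. The leaves had been scraped, so for the jasmonate and wound lists a response to scraping cannot be told apart from tissue.

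At the entry to phenylpropanoids 2 of 5 genes rose and 2 fell (2 and 2 adjusted over the list alone; camera adjusted p = 0.975), with PAL3 (Solyc09g007910) up by 1.94 and 4CL (Solyc03g117870) down by 2.12 on the log2 scale; PAL5 (Solyc09g007920), which also rose, lost its call without collection 2 (adjusted p = 0.0655). Of 8 genes used as references in quantitative PCR, 6 rose and 0 fell (6 adjusted over the list alone; camera adjusted p = 0.0987). Among them, a gene listed as ubiquitin (Solyc07g064130) rose by 1.17, a call lost without collection 2 (adjusted p = 0.0519). The actin gene ACT (Solyc03g078400) had a log2 fold change of -0.14 and was not called, but with library size alone it was (log2 -0.38, adjusted p = 0.0486), and a gene listed as EF1alpha (Solyc06g005060), up by 0.78, then lost its call (adjusted p = 0.0569), as did a gene listed as actin (Solyc11g005330, adjusted p = 0.208), which gives 4 risen and 1 fallen.

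A hypothesis was that genes far higher in 1 tissue lie side by side more often than chance. Of 553 genes on chromosomes 1 to 12 with a log2 fold change of at least 5 towards trichome, 87 neighbouring pairs were found, against a mean of 10.9 and a maximum of 26 in 10000 shuffles within chromosomes (permutation p = 1e-04, the smallest they can give). The same held towards leaf, with 283 pairs among 1923 genes against a mean of 132.4 and a maximum of 178 (permutation p = 1e-04). The longest run towards trichome held 9 genes on chromosome 5, from Solyc05g046140 to Solyc05g046220. Tandem gene copies were not separated from other neighbours, so how many of these pairs they form is not known.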
